A study of Danio rerio with 6 samples.

How the data were processed

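Total RNA from 50 pooled zebrafish embryos per sample was extracted with a spin-column kit and sequenced on an Illumina platform after standard library preparation, per the labels' protocols. The 6 libraries fall into 2 groups of 3, wild type and MZdgcr8, taken from the genotype given for each sample, and the replicate numbers come from the sample titles. The deposited table gives FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for each gene and library, as scaled by the authors, per the file headers. It also gives deposited counts, as whole numbers per gene and library with no normalization, per the file headers. HISAT2 2.0, StringTie 1.3.0 and Bowtie 0.12.2 are named in the submitters' processing notes without their roles. The build named there is mm8, a mouse build, while the gene identifiers are Ensembl zebrafish identifiers; the zebrafish build and annotation used are not given in the sources used here, so no coordinates are printed. Gene names are those of the table, and 99 of 99 identifiers were matched in a separate table of gene names. The name matr3l1.1 belongs to 2 of the identifiers, and genes with close paralogs, such as ptpn4a and ptpn4b, are uncertain because the treatment of shared reads is not given in the sources used here.

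The table lists 99 genes, so its count totals (358811 to 576050 per library) are not library depths. For a gene, the ratio of count to FPKM depends on its length and on library depth. Over 58 genes with more than 200 counts in every library this ratio gave the relative depth of the libraries, with a largest deviation of any gene of 0.0048 on the log2 scale. Relative depth was 1.13, 1.04 and 0.797 in wild type replicates 1, 2 and 3, and 1.07, 1.14 and 0.872 in MZdgcr8 replicates 1, 2 and 3. These depths were used as library sizes in place of the column totals. None of the 594 count values is 1, 2 or 3, while 11 are 4 and 33 are 0, so 1 count may not be 1 read. For that reason no counting intervals or detection floors are given, genes at 0 are said to be listed at 0, and the tests were repeated with counts divided by 4.

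The tests, the samples in them, the expression minimum, the alternatives, 24 gene lists and the rule for naming genes were fixed before the data were examined, except where a choice is said to have been made afterwards. The plan assumed FPKM values alone and limma on log2(FPKM + 1), with edgeR in its place if the table held counts. As it did, the planned comparison was fitted with edgeR 4.0.16 (quasi-likelihood, R 4.3.3) on genes with a mean of at least 1 FPKM over the 6 libraries, which left 67 genes and set 32 aside. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Fold changes from edgeR are ratios of MZdgcr8 to wild type at the authors' depth, and standard errors were derived from the fold change and its F statistic. limma 3.58.1 and DESeq2 1.42.0 were run as alternatives, together with other pseudocounts (0.1 and 5, with limma), expression minima, TMM, RLE, median and quantile scaling, robust empirical Bayes, sample weights, a minimum fold change and the removal of each replicate.

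The replicate numbers were checked for pairing from the data, since the labels do not say what a number stands for. Deviations from the group means correlated over genes at 0.77, 0.76 and 0.80 for replicates 1, 2 and 3 of the 2 genotypes, so the numbers were treated as pairing the samples, and the fit with the replicate number as a block is given beside the fit without it. The pairing rests on replicate 3, because deviations also correlated between wild type replicate 1 and MZdgcr8 replicate 2 (0.71) and between wild type replicate 2 and MZdgcr8 replicate 1 (0.82). Replicates 1 and 2 correlated at 0.996 within each genotype (Pearson, log2(FPKM + 1)), against 0.901 and 0.891 for wild type and 0.805 and 0.801 for MZdgcr8 with replicate 3. They were kept as separate samples because the labels list them as such. Their counts were not identical, with a chi-square per degree of freedom of 28.9 in wild type and 22.4 in MZdgcr8 (7.22 and 5.61 with counts divided by 4), but repeat libraries of 1 RNA can also exceed counting noise, so this does not show that they are independent. After this was seen, fits of replicates 1 and 2 alone, of replicate set (replicate 3 against the others) as a term, and of the interaction of genotype and set were added.

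The naming rule took the 10 largest changes in each direction among genes past the threshold whose groups do not overlap, passing over placeholder symbols, and up to 4 members of each list. It named no gene from the unblocked fit outside the lists, so it was also applied to the blocked fit and to replicates 1 and 2, a choice made after the data were seen. A gene that the rule names is not reported here. The genes ell in the blocked fit, srrm1, and those given for replicate 3 fall outside the rule and were chosen after their values were seen. Terms of gene ontology listed in the deposited table were tested with camera (correlation 0.01) and fry for the 14 terms with at least 5 tested genes. The scripts were tested on simulated counts for the 67 genes, with 14 genes changed in each of 20 runs. Of genes changed 2-fold, 0.357% were recovered in the fit of 6 libraries without the block, 52.5% with the block and 100% in replicates 1 and 2, and of genes changed 4-fold 36.8%, 99.3% and 100%. At most 0.6 false calls per run were made. The simulated biological coefficient of variation was 25.6%, from the blocked fit, for both fits of 6 libraries, and 8.4% for replicates 1 and 2. These rates therefore do not rank the fits by power. Those of replicates 1 and 2 hold only if their small spread is that of independent samples, which is not known. A search of 3' untranslated regions for microRNA seed matches needs transcript sequences and was not run.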

Results

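Messenger RNA was profiled by RNA sequencing in whole zebrafish embryos of the AB strain at 4.5 hours post fertilization, when the blastoderm has spread over 30% of the yolk (the 30% epiboly stage). Wild-type embryos were compared with MZdgcr8 embryos, which lack both the maternal and the zygotic supply of Dgcr8, the RNA-binding partner of Drosha that is required for the first cleavage of canonical microRNA precursors. Each genotype had 3 libraries, and each library was made from 50 pooled embryos. The table used here lists 99 genes, so every count of genes below is a count within that table and not a genome-wide one. All of these genes have low-numbered Ensembl identifiers, so the absence of a gene from the table is not a result. Counts summed over these genes ran from 358811 to 576050 per library. Relative library depth ran from 0.797 in wild type replicate 3 to 1.14 in MZdgcr8 replicate 2. A mean of at least 1 FPKM was reached by 67 genes, which were tested. The transcript of dgcr8 was not analysed here, so the labels were not checked against the targeted gene.

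The comparison of MZdgcr8 with wild type asks which messenger RNAs differ in level when embryos reach epiboly without Dgcr8. The transcript of dicer1, which encodes the nuclease acting after Dgcr8 in microRNA production, was present at 31.6 ± 4.97 FPKM (SD, n = 3) in MZdgcr8 embryos and at 10.5 ± 5.15 FPKM (SD, n = 3) in wild type. The tyrosine phosphatase gene ptpn4b was at 15.0 ± 6.10 against 4.96 ± 3.17 FPKM, and dcaf8, a substrate receptor of cullin ubiquitin ligases, was at 18.7 ± 7.69 against 7.12 ± 1.58 FPKM. For ell, which encodes an RNA polymerase II elongation factor, the means were 37.4 ± 22.8 and 12.7 ± 7.50 FPKM. In the planned edgeR fit, which has no block, 0 of the 67 tested genes passed the threshold. With the replicate number as a block, 5 passed, these 4 among them, and all 5 were higher in MZdgcr8 embryos. The pairing behind the block was inferred from these same data and rests on replicate 3.

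In that blocked edgeR fit the fold changes were 3.44 for ptpn4b (log2 1.78 ± 0.26 SE, adjusted p = 0.0321) and 3.33 for dicer1 (log2 1.73 ± 0.29, adjusted p = 0.0427). They were 2.79 for ell (log2 1.48 ± 0.18, adjusted p = 0.0321) and 2.49 for dcaf8 (log2 1.32 ± 0.20, adjusted p = 0.0321). Each of these 4 genes was higher in 3 of 3 pairs, but the fit of the same pairs picked them, so this is no separate evidence. Genes without a call in this fit also went 1 way in 3 of 3 pairs, such as gtf2e1 and ptpn4a (higher) and bysl, nfyal and slc6a13 (lower). For ptpn4b, dicer1 and dcaf8 all 3 MZdgcr8 values also lay above all 3 wild-type values. For ell they did not, since MZdgcr8 replicate 3 (11.1 FPKM) lay below wild type replicates 1 (13.5 FPKM) and 2 (19.8 FPKM). No gene was called lower in this edgeR fit, while with the block DESeq2 called 5 of 13 lower and limma with sample weights 22 of 34. With replicate set (replicate 3 against the others) in place of the block, edgeR called 26 genes, 11 higher and 15 lower. Among the 67 genes, 12 had groups that did not overlap over the 6 libraries, 6 higher and 6 lower, where chance gives 6.7.

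Without the block, 0 of the 67 genes passed edgeR's quasi-likelihood test, and DESeq2 and limma on log2(FPKM + 1) also called 0. In limma, quantile normalization gave 3 calls, and sample weights gave 38, 14 higher and 24 lower. The weighted log2 changes lay near those of replicates 1 and 2 alone (-2.26 and -2.31 for krt97, 1.32 and 1.36 for dicer1). The 38 calls may therefore rest mostly on those libraries. The smallest adjusted p in edgeR was 0.559, and 5 genes had an unadjusted p under 0.05. Of these 5, 4 were higher in MZdgcr8, dicer1, dcaf8 and gtf2e1 among them. The other, srrm1, encodes a splicing coactivator and was at 120 ± 9.41 FPKM against 143 ± 4.05 FPKM in wild type. Some other splits of the 6 libraries into 3 and 3 gave more such genes (14 and 10). These splits placed both replicate 3 libraries on the same side, so they carry the difference of replicate 3 from the other replicates. The other splits that part the replicate 3 libraries each gave 0, but the splits are too few for a share under 0.05. The biological coefficient of variation was 54.5% in the fit without the block, 25.6% with the block and 8.4% within replicates 1 and 2. With medians of the libraries set equal, the blocked fit called 6 genes higher and 36 lower, in place of 5 and 0, and with no filter on low values it called 0. A trend with transcript length was fitted in replicates 1 and 2 and then removed from all MZdgcr8 libraries, replicate 3 included. In the blocked edgeR fit this removal took dicer1 from log2 1.73 to 1.39 and its adjusted p from 0.0427 to 0.0598.

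**Figure D1:**
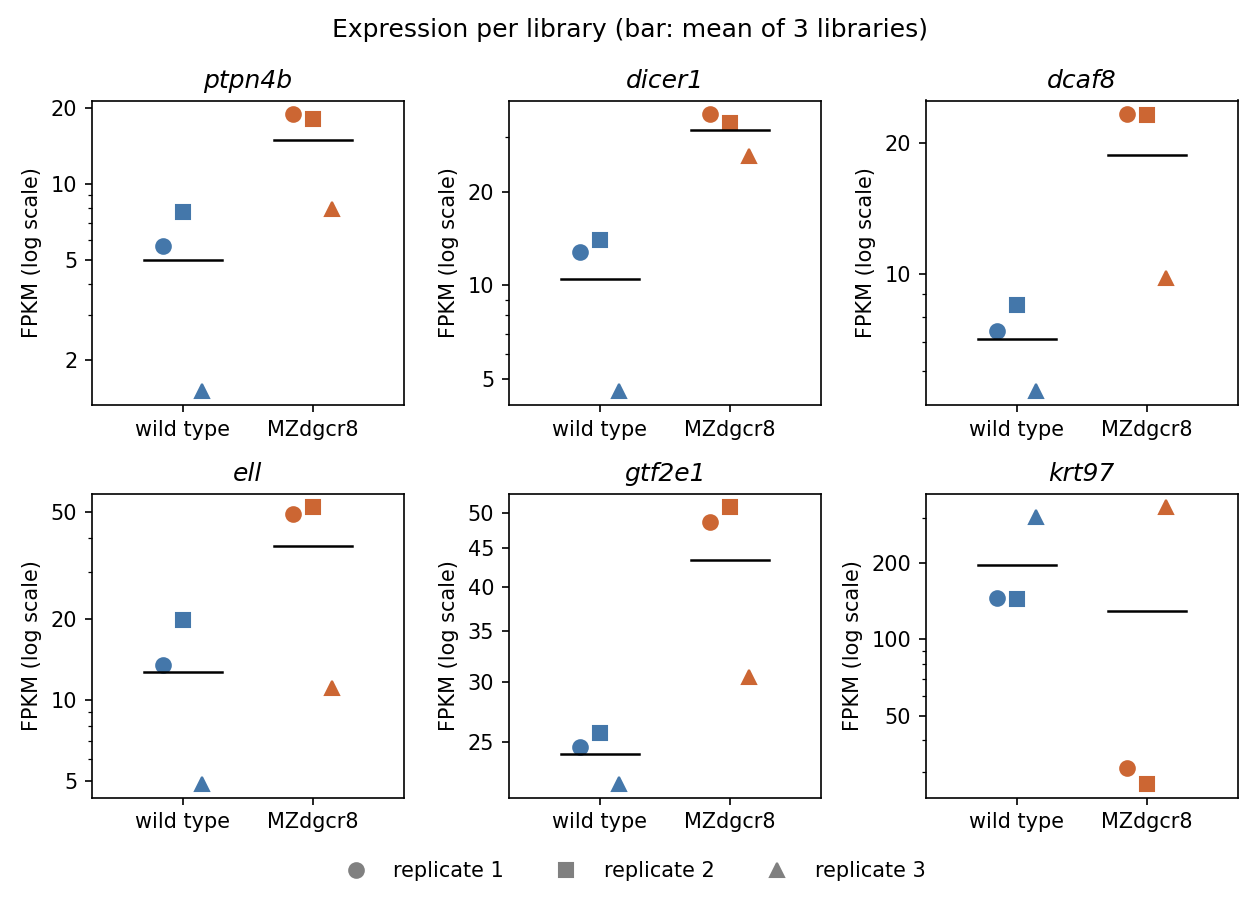
FPKM on a log axis for ptpn4b, dicer1, dcaf8, ell, gtf2e1 and krt97 in each wild-type (blue) and MZdgcr8 (orange) library, with the replicate number as the symbol and the group mean as a bar. The MZdgcr8 values of dicer1 (26.0 to 35.5 FPKM) lie above its wild-type values (4.57 to 14.0 FPKM), while krt97 in replicate 3 is at 302 FPKM in wild type and 331 FPKM in MZdgcr8.

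Replicates 1 and 2 of each genotype were close to each other, and within them the genotypes were separated for many more genes. The edgeR fit of these 4 libraries called 43 of 67 genes, 16 higher and 27 lower in MZdgcr8, and the 5 genes of the blocked fit were among them. Among the increases, ell rose by 1.60 ± 0.17 SE on the log2 scale (3.04-fold). The orphan nuclear receptor gene nr4a1 (log2 1.54 ± 0.14) and dcaf8 (1.54 ± 0.10) rose by the same amount. The phosphatase paralogs ptpn4a and ptpn4b rose by 1.52 ± 0.21 and 1.47 ± 0.15 on the log2 scale, with the caveat that reads may be shared between them. Next came dicer1 (1.36 ± 0.07, 2.56-fold), TMEM267 (1.22 ± 0.11), the thyroid hormone receptor gene thraa (1.13 ± 0.14) and gtf2e1, a subunit of the general transcription factor TFIIE (0.98 ± 0.07). Adjusted p in edgeR ran from 2.27e-05 for dicer1 to 0.00129 for ptpn4a over these 9 genes.

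The keratin gene krt97 showed the largest decrease in replicates 1 and 2. It was at 145 and 144 FPKM in wild type and at 31.1 and 26.9 FPKM in MZdgcr8, 4.97-fold lower (log2 -2.31 ± 0.09 SE, adjusted p = 1.08e-05 in edgeR). The gene osgepl1, which encodes a mitochondrial tRNA-modifying enzyme, was 2.29-fold lower (log2 -1.20 ± 0.11). Smaller decreases were those of the synaptophysin-like gene sypl2b (log2 -0.90 ± 0.17), the GABA transporter gene slc6a13 (-0.89 ± 0.19), dzip1 (-0.68 ± 0.12) and slc35a5 (-0.66 ± 0.11). The gene nfyal fell by 0.59 on the log2 scale, the tRNA-modifying lcmt2 by 0.57, the ribosome assembly factor bysl by 0.53 and the deubiquitinase gene usp49 by 0.49. Over the 10 genes, adjusted p in edgeR ran from 1.08e-05 for krt97 to 0.00711 for slc6a13 and lcmt2. A change of at least 1 on the log2 scale was reached by 11 of the 43 genes, 9 higher and 2 lower. The split of calls depended on the scaling: TMM gave 21 higher and 20 lower, RLE 22 and 19, and equal medians 11 and 51. The labels do not say that replicates came from separate clutches, so p-values measure only the spread between these libraries, which may be technical.

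Replicate 3 stood apart from replicates 1 and 2 in both genotypes. With genotype in the model, 52 of 67 genes differed between replicate 3 and the other replicates, 10 higher and 42 lower in replicate 3. With TMM scaling the split was 19 higher and 27 lower. The gene mctp2a was 15.7-fold higher in replicate 3 (log2 3.97 ± 0.45 SE, adjusted p = 0.000898 in edgeR), with 2.87 FPKM in wild type and 5.0 FPKM in MZdgcr8 against at most 0.374 FPKM in the other 4 libraries. Values of krt97 were 5.53-fold higher (log2 2.47 ± 0.57) as an average of unlike shifts, from 145 and 144 to 302 FPKM in wild type and from 31.1 and 26.9 to 331 FPKM in MZdgcr8, and dzip1 and bysl rose by 1.45 ± 0.15 and 1.42 ± 0.09. The receptor gene thraa was 10.6-fold lower (log2 -3.41 ± 0.48), and the shifts of mctp2a, slc1a4 and thraa also differed between the genotypes (interaction log2 1.48, 1.78 and -1.67). The genes unk and slc1a4 were lower by log2 -2.53 ± 0.18 and -2.42 ± 0.54. On a principal component analysis of log2(FPKM + 1), the first component held 74.7% of the variance and separated replicate 3 from the rest, and the second held 18.9% and separated the genotypes.

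The genotype difference itself was compared between replicate 3 and replicates 1 and 2. An interaction of genotype and replicate set passed the threshold for 28 genes, and for 15 of them the difference had opposite signs. The decrease of krt97 seen in replicates 1 and 2 was not seen in replicate 3, where the values were 302 FPKM in wild type and 331 FPKM in MZdgcr8 (interaction log2 2.45 ± 0.13 SE, adjusted p = 6.34e-05 in edgeR). The transcript of nr4a1 was higher in MZdgcr8 in replicates 1 and 2, and in replicate 3 it was at 0.283 FPKM against 0.893 FPKM in wild type (interaction log2 -3.19 ± 0.27, adjusted p = 0.000284 in edgeR). For dicer1 the difference was larger in replicate 3 (interaction log2 1.15 ± 0.11), and so it was for ptpn4b (0.94 ± 0.27). For dcaf8 it was smaller (-0.68 ± 0.18). Of the 43 genes called in replicates 1 and 2, 31 had the same sign in replicate 3, 11 of 16 among the higher and 20 of 27 among the lower. Most genes without a call also had the same sign in both sets, so these counts are a weak measure of replication. Replicate 3 has 1 library per genotype, so the error of the interaction comes from replicates 1 and 2 alone.

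**Figure D2:**
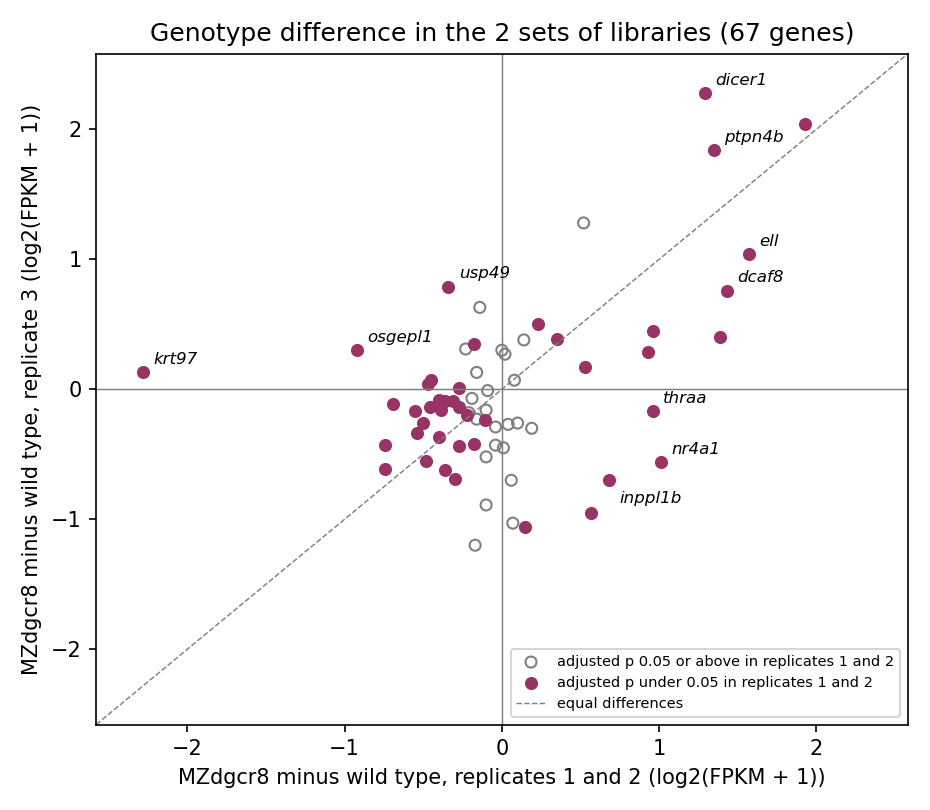
Difference in log2(FPKM + 1) between MZdgcr8 and wild type for each of 67 genes, as the mean of replicates 1 and 2 (x axis) and in replicate 3 (y axis), with filled points for genes past the threshold in replicates 1 and 2. The points of ptpn4b (1.35 and 1.84) and dicer1 (1.29 and 2.28) are high on both axes, while krt97 (-2.28 and 0.13) and nr4a1 (1.01 and -0.56) lie apart from the dashed line of equal differences.

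Of the 24 gene lists fixed for this stage and mutant, 4 had a gene in the table, 1 each, and no list could be tested as a group. The microRNA pathway list was represented by dicer1, which did not pass the unblocked edgeR test over all genes (adjusted p = 0.559, unadjusted p = 0.00906). With 1 tested gene, adjustment over the list alone leaves the unadjusted p as it is, so this is no test of the pathway. The list of enveloping layer and epidermal genes, which covers the outermost cell layer of the embryo, was represented by krt97 (197 ± 91.0 FPKM in wild type, 130 ± 174 FPKM in MZdgcr8, n = 3 each, unblocked log2 -0.60 ± 0.99). With the block its log2 change was -1.54 ± 0.61 SE, with no call (unadjusted p = 0.0603 in edgeR). It was called lower with the block in DESeq2 (-1.54), with median scaling (-1.97), with sample weights in limma (-2.06) and without replicate 2 (-1.04) or replicate 3 (-2.32), and without the block with sample weights (-2.26). Leaving out 1 library moved the unblocked value from -0.12 without MZdgcr8 replicate 2 to -2.76 without MZdgcr8 replicate 3, and it passed the threshold in the latter. The cytoskeleton and epiboly list was represented by the non-muscle myosin gene myh9b, at 24.9 ± 10.6 FPKM in wild type and 20.5 ± 1.88 FPKM in MZdgcr8, with no call in edgeR with or without the block at the authors' depth, and a call as lower with the block and median scaling (log2 -0.63). The iron exporter gene slc40a1, on the yolk syncytial layer list, was below the expression minimum at 0.185 ± 0.161 and 0.319 ± 0.0542 FPKM. With no filter, the edgeR fit of replicates 1 and 2 called slc40a1 higher (log2 1.90, adjusted p = 0.00109). In replicate 3 it was lower in MZdgcr8, at 0.263 FPKM against 0.37 FPKM in wild type. In the unblocked fit neither krt97 nor myh9b passed when adjusted over the list alone.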

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

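The tests of a swap of labels and of the spread between libraries were chosen only after the results were seen; the other tests in this part were set down before their results. The difference between MZdgcr8 and wild type changed between replicates 1 and 2 and replicate 3 for 28 of 67 genes, by an interaction term in edgeR. Among genes named here, the interaction was positive for krt97 (log2 2.45), slc1a4 (1.78), osgepl1 (1.56), usp49 (1.53), mctp2a (1.48), dicer1 (1.15) and ptpn4b (0.94). It was negative for nr4a1 (-3.19), inppl1b (-2.36), thraa (-1.67), TMEM267 (-0.86), slc35a5 (-0.80), myh9b (-0.78), dcaf8 (-0.68) and gtf2e1 (-0.52). For dicer1, ptpn4b and slc1a4 the increase was larger in replicate 3, and for slc35a5 the decrease was larger. For dcaf8, TMEM267 and gtf2e1 the increase was smaller in replicate 3, with the same sign. The sign differed for krt97, osgepl1, usp49, mctp2a, nr4a1, inppl1b, thraa and myh9b, the last with a difference near 0 in replicates 1 and 2 (0.06).

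The first pattern weighed is that replicate 3 stands apart in both genotypes, with 52 genes called against replicates 1 and 2 and a shift that correlated at 0.80 between the genotypes over genes. Lower depth of the replicate 3 libraries is argued against by thinning all libraries to the shallowest, which left 52 calls. Relative depth ran only from 0.797 to 1.14, so few calls could be lost. The thinning removed count units, which may not be reads, so it covers depth only as the counts give it. A scaling difference shared by all genes is argued against by TMM scaling, with 46 calls, 19 higher and 27 lower in replicate 3. A bias with transcript length is argued against by the correlation of the shift with relative length (Spearman -0.15, bootstrap 95% interval -0.39 to 0.11). A different developmental age of the replicate 3 embryos stays open, since 1 gene, krt97, was tested on the stage and layer lists, and a batch of embryos or libraries stays open as well because the labels give none.

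The second pattern is the change of the genotype effect between replicate sets. A scaling difference is argued against by TMM scaling, which gave 36 genes with an interaction. Lower depth is argued against by thinning, which gave 34, with the limit on count units stated above. A swap of the replicate 3 labels is argued against by the correlation of the genotype effects over genes (Pearson 0.49, bootstrap 95% interval 0.17 to 0.71), to which dicer1 and ptpn4b contribute with increases in both sets; the Spearman value was 0.25 (-0.01 to 0.48), where a swap predicts a negative correlation. A larger spread between libraries than replicates 1 and 2 show cannot be told apart from a changed effect of Dgcr8 loss, because the fit has 2 residual degrees of freedom, both from replicates 1 and 2, and replicate 3 has 1 library per genotype.

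The third pattern is that the genotype effect in replicates 1 and 2 was higher for genes with longer transcripts (Spearman 0.37, bootstrap 95% interval 0.14 to 0.58), while in replicate 3 the correlation was 0.14 (-0.12 to 0.38). As the whole cause of the calls, a length bias is argued against by the removal of the trend, after which 35 of the 43 genes stayed past the threshold in the same direction, 14 of 16 higher and 21 of 27 lower. The removed trend was at most 0.42 on the log2 scale, too small to account for the larger changes. For genes with such changes, staying past the threshold was therefore nearly certain in advance. For the blocked fit, the same trend, fitted in replicates 1 and 2, was removed from all MZdgcr8 libraries, replicate 3 included. In that fit 4 of the 5 genes stayed among 7 calls, 5 higher and 2 lower, with gtf2e1 gained as higher and srrm1 and nfyal as lower. The call of dicer1 ended there, with log2 1.73 ± 0.29 SE before and 1.39 ± 0.29 after, a smaller change with the same standard error (adjusted p = 0.0427 and 0.0598 in edgeR). A length-related part of the differences, technical or from longer untranslated regions, stays open, and no biological explanation was tested.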

How the results depend on the processing

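For the unblocked fit, DESeq2, TMM, RLE, counts divided by 4, replicates 1 and 2 alone and replicate set as a term were chosen after the data were seen. So were all alternatives of the blocked fit and of replicates 1 and 2. The unblocked limma fit on log2(FPKM + 1) had been planned for a table without counts, and it was run beside edgeR once counts were found. The others were planned. Without the block, the 0 calls became 3 (2 higher, 1 lower) with quantile normalization, 38 (14 and 24) with sample weights and 2 (2 higher) with RLE scaling. The replicate block gave 5 (5 higher), replicates 1 and 2 alone 43 (16 and 27), and replicate set as a term 26 (11 and 15). Leaving out 1 library gave 0 to 3 calls (0 to 2 higher, 0 to 1 lower), with 3 only without MZdgcr8 replicate 3. For a split of the 6 libraries into 3 and 3, the real value was 0 and the highest other 0, so 10 of 10 splits were as large, and 10 splits are too few for a share under 0.05.

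With the block, the 5 calls (5 higher, 0 lower) became 0 (0 higher) with no filter, where more genes are tested, 8 (2 lower) at a mean of at least 5 FPKM, 42 (36 lower) with median scaling and 1 (1 higher) with quantile normalization. Sample weights gave 34 (12 and 22) and DESeq2 13 (8 and 5). Leaving out 1 pair gave 4 to 35 calls (4 to 15 higher, 0 to 20 lower), with 8 without replicate 2 and 35 without replicate 3. Over 16 alternatives ell and ptpn4b passed in 14, dicer1 in 13 and dcaf8 in 11, all with positive log2 changes, from 0.89 for dcaf8 to 2.07 for ptpn4b. Their adjusted p reached at most 0.129 (dcaf8, limma with quantile normalization). Of the 4 splits that part every pair, 1, the real one, gave 5 calls and the highest other gave 0, which is too few splits for a share under 0.05. The block changed no list test, as none had 5 tested genes.

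In replicates 1 and 2, a minimum change of 1 on the log2 scale left 11 of 43 calls (9 higher, 2 lower), and median scaling moved the lower calls from 27 to 51. Leaving out 1 library gave 39 to 40, but 1 genotype then has a single library and the error comes from the other alone, so this does not measure stability. Median scaling moved the median log2 change by -0.46 there, against 0.11 for TMM and 0.14 for RLE, and called 39 of the same genes, TMM 36 and RLE 35. The log2 change of myh9b, which was called with the block and median scaling (-0.63), turned from negative to 0.06 with sample weights and 0.06 in replicates 1 and 2 alone. Leaving out 1 library gave -0.47 to 0.13, positive without wild type replicate 3, and with the block leaving out 1 pair gave -0.40 to 0.06, positive without replicate 3. For dcaf8, dicer1, krt97, myh9b and ptpn4b, over both fits of 6 libraries, alternatives gained a call 25 times, lost one 10 times and kept sign and side of the threshold 150 times. Beyond the fewer genes or libraries, the cause of these changes was not tested. Tests of dgcr8, of gene lists and of microRNA seed matches, with their alternatives, were not run.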

Other observations

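Below the expression minimum, some genes had values that were far apart between the genotypes, and these were picked after their values were seen. The gene creg2 was at 1.32 ± 0.0646 FPKM (SD, n = 3) in wild type and 0.41 ± 0.133 FPKM in MZdgcr8, and the neural adhesion gene cntn2 at 1.19 ± 0.464 and 0.594 ± 0.231 FPKM. With no filter and with the block, edgeR gave adjusted p = 0.0783 for creg2 and 0.0839 for cntn2, and without the block 0.190 and 0.612. The ankyrin and armadillo repeat gene ankar was at 0.180 ± 0.0517 and 0.0309 ± 0.011 FPKM. The opsin gene opn1mw4 was at 0.25, 0.216 and 0.0928 FPKM in wild type, from 31, 25 and 8 counts, and was listed at 0 in all 3 MZdgcr8 libraries, and reads could be shared with other green opsin genes. The homeobox gene hoxb2a was at 0.35 and 0.368 FPKM in MZdgcr8 replicates 1 and 2 and at 0.0643 FPKM in MZdgcr8 replicate 3, against 0.0495 to 0.102 FPKM in wild type. With no filter, the edgeR fits of 6 libraries called none of these 5 genes, and the fit of replicates 1 and 2 called all 5, creg2, cntn2, ankar and opn1mw4 as lower and hoxb2a as higher (adjusted p of at most 0.00969), among 51 calls (21 higher, 30 lower).

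Among 14 gene ontology terms with at least 5 tested genes, hydrolase activity had the lowest camera p in both fits. Its 5 tested genes are dicer1, ptpn4a, ptpn4b, usp49 and inppl1b, the last encoding an inositol phosphatase. In the blocked fit dicer1 and ptpn4b were called higher (camera adjusted p = 0.0233, limma and edgeR), and with an estimated correlation the adjusted p = 0.937. In replicates 1 and 2, dicer1, ptpn4a, ptpn4b and inppl1b rose and usp49 fell (camera adjusted p = 0.0629 with limma and edgeR). In replicate 3 inppl1b was lower in MZdgcr8 (0.538 FPKM against 1.51 FPKM in wild type) and usp49 was higher. The test fry in limma does not compare a term with other genes. In the blocked fit, fry gave hydrolase activity an adjusted p of 0.0751 for 1 direction and 0.0215 for either. Metal ion binding had a lower fry value for either direction (0.00403). The paralogs ptpn4a and ptpn4b are uncertain as separate members.

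A hypothesis from these data is that part of the genotype difference and of the replicate 3 shift may lie along 1 axis of variation, in opposite directions. Over 67 genes, which are not independent replicates, the genotype effect in replicates 1 and 2 correlated at -0.44 with the replicate 3 shift (Pearson, bootstrap 95% interval -0.63 to -0.18; Spearman -0.35), with krt97, ell and ptpn4b going opposite ways. In sign alone, 35 of 67 genes had opposite effect and shift. Without krt97, ptpn4b, dicer1, ell and dcaf8 the correlation was -0.29. Of 1000 simulated runs without a genotype effect, 0 reached the correlation of -0.44 (lowest -0.37). The runs drew each gene independently, with the spread of replicates 1 and 2 (biological coefficient of variation 8.39%). They therefore cannot decide on noise that many genes of a library share, which stays open. The effect and the shift also share the libraries of replicates 1 and 2. A change of MZdgcr8 in those replicates alone enters the effect and, with opposite sign, the shift, which by itself gives a negative correlation. For krt97 the effect was -2.28 in replicates 1 and 2 and 0.13 in replicate 3, with a shift of 2.27. The runs held no such interaction, which 28 genes showed, so they cannot decide on it. Transcript length is argued against by a Spearman correlation of -0.32 given length. The test within replicate 3 gave -0.07 (interval -0.28 to 0.17), which leaves the hypothesis open.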
